A study of Homo sapiens with 11 samples.

How the data were processed

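RNA-seq was measured in 11 libraries of ARP1, an established human multiple myeloma line that makes IgA kappa. Per the labels, PHF19 overexpression and empty vector cells were made with a lentivirus packaged in HEK293T cells, and cells overexpressing PHF19 were sorted before RNA extraction. The scramble and shRNA samples carry the same treatment text, which names only the PHF19 and empty vector plasmids, so how the shRNA was delivered is unknown. Groups were taken from the sample titles, because the genotype tag of the scramble and shRNA samples repeats the overexpression wording. Whether replicates were separate cultures, and whether the 3 shRNA libraries carry the same hairpin, is not given in the sources used here. The sample descriptions end in the letter F for both overexpression libraries and in S for all empty vector libraries, with no meaning given, so whatever these letters mark cannot be told apart from the group.

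The authors' values came in 2 tables, which hold abundances recorded here as FPKM, deposited by the authors after normalisation for gene length and depth. The headers name no unit, and FPKM, RPKM and TPM could not be separated from the values alone. Reads were aligned with TopHat (version not given) to hg19, per the submitters' processing notes. The quantifier, the annotation and the authors' gene filter are not given in the sources used here. Each table also holds a p-value per gene from the authors' own test, per the file headers, with no statement of the test. The overexpression table lists 11062 genes, and 14458 genes are listed for knockdown, the latter rounded to 2 decimals by the authors. Both are partial gene lists, and MCL1 is not among the genes of the overexpression table. Among the knockdown genes, 24 symbols had been turned into dates and were left unmatched. No coordinates are given, because the reference at hand is of another build than hg19. The tables carry no counts, so read depth and counting error are unknown and no interval or detection floor was computed.

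The 2 tables were normalised separately, so overexpression was compared with empty vector and shRNA with scramble, each within its own table. Values were taken as log2(value + 1) with no further normalisation between libraries. Genes with a value of at least 1 in at least as many libraries as the smaller group holds were tested, 10279 in the overexpression arm and 10900 in the knockdown arm. The test was limma-trend with robust variances (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are differences of mean log2(value + 1), treated minus control, with limma's standard error (SE). Levels are arithmetic means ± SD. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for the remaining tables and plots.

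Before the data were examined, 35 gene lists, the named-gene rule and most alternatives were fixed. Lists with at least 5 members tested were compared with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of the overexpression arm and the 29 of the knockdown arm. Camera with an estimated correlation and fry, which tests whether the members move 1 way on balance, were run beside it. Calls of list members were also adjusted over the list alone. The 8 lists described for overexpression and the 12 for knockdown were chosen after the results were seen, as those past the threshold plus Polycomb and apoptosis lists.

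Named genes were, in each arm, PHF19, EZH2, BCL2L1, MCL1 and HIF1A, the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap and a mean of at least 1, and up to 4 members of each described list with the smallest adjusted p. Uncharacterised loci and immunoglobulin segments were left out. Because many genes of the overexpression table are listed at exactly 0 in whole groups, the same rule was applied again to genes with no 0, which was decided after the values were seen. Where a gene is listed at 0 in a group, single library values are given and no fold. Genes that share reads with close copies, such as HBA1, ATAD3B and the NME1-NME2 readthrough, are uncertain.

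The numbers 1 to 3 occur in both knockdown groups. Deviations from the group means correlated across genes at 0.341, 0.270 and 0.273 for libraries with equal numbers. For the other pairs the correlations were -0.277 to 0.0936. A pairing by number was therefore treated as possible, and the reported fit does not use it. This pairing comes from the data, since no label states it. The fit with the replicate number as a block is an alternative, and its value stands beside a result where it changes the call.

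Alternatives were limma without trend and robust variances, quantile normalisation, median-of-ratios scaling, no filter, a filter at 5, pseudocounts of 0.1 and 0.5, library weights, each library left out in turn, stricter thresholds, and the block. Chosen after seeing the data were the fits that leave out genes listed at 0, that treat such zeros as missing, that combine this with leaving out overexpression replicate 2 or empty vector replicate 5, and the blocked fit without replicate 1 of both knockdown groups.

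The procedure was tested on simulated data made from the real gene means, in 3 runs with 200 changed genes each. For the knockdown design (10874 genes), 40.8% of 1.5-fold, 96.02% of 2-fold and 99.5% of 4-fold changes were recovered, with 47 false calls over all runs. For the overexpression design (8665 genes with no 0) the shares were 2.99%, 38.8% and 95.96%, with 24 false calls. The simulated noise holds no shift shared by a whole library. In the real fit of these 8665 genes 0 passed, although FOS (log2 fold change 4.42), DUSP1 (3.05) and EGR1 (2.67) were among them. The simulated shares may thus be too high for the real libraries. A list of 30 genes shifted by 0.5 (log2) was called in 3 of 3 runs in each design, and 0 of 300 unshifted lists were called. The simulated genes vary independently, while estimated correlations within lists reach 0.790 in the real data, so this says little about false list calls.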

Results

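RNA-seq abundances were collected from ARP1 myeloma cells in 4 groups: empty vector (n = 3), PHF19 overexpression (n = 2), scramble control (n = 3) and PHF19 shRNA (n = 3). PHF19 is an accessory subunit of Polycomb repressive complex 2 (PRC2), whose catalytic subunit EZH2 methylates histone H3. The series title concerns PHF19 in growth, drug resistance and EZH2 phosphorylation in multiple myeloma, so genes of Polycomb, the cell cycle and apoptosis were listed in advance. Abundances are length- and depth-normalised values of FPKM type whose unit the headers do not name. Read depth is unknown. The listed abundances summed to 425155 to 426112 in empty vector libraries, 498485 and 502349 in overexpression libraries, 470294 to 526068 in scramble libraries and 501348 to 524966 in shRNA libraries. Libraries correlated at 0.953 to 0.993 in the knockdown table (Pearson, log2 values, across genes) and at 0.760 to 0.831 in the overexpression table, or 0.943 to 0.987 there without genes listed at 0 in any library. In the knockdown arm shRNA replicate 1 stood apart: it lay at 35.2 on the first principal component, against 8.46 and 10.6 for shRNA replicates 2 and 3 and -21.2 to -15.3 for scramble libraries, and correlated with every other library at 0.953 to 0.973, while shRNA replicates 2 and 3 correlated at 0.993.

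PHF19 was measured first as a check of the labels. In the overexpression arm PHF19 rose from 115 ± 4.12 (SD, n = 3) in empty vector to 220 ± 9.63 (n = 2) in overexpression libraries, a log2 fold change of 0.93 (SE 0.094, limma adjusted p = 0.0438). In the knockdown arm PHF19 was 129 ± 20.3 (n = 3) in scramble and 95.3 ± 17.5 (n = 3) in shRNA libraries, with a log2 fold change of -0.44 (SE 0.17) and no overlap between groups. That difference did not pass the test (adjusted p = 0.147) and did with the replicate number as a block (adjusted p = 0.0445). The authors' own p for PHF19 was 4.38e-12 in the overexpression table and 2.03e-46 in the knockdown table, from a test that is not given in the sources used here. The overexpression call ended when genes listed at 0 in any library were left out (adjusted p = 0.156), under quantile normalisation (0.75 on the log2 scale, adjusted p = 0.166) and without any single library other than empty vector replicate 5 (adjusted p 0.149 to 0.264).

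**Figure D1:**
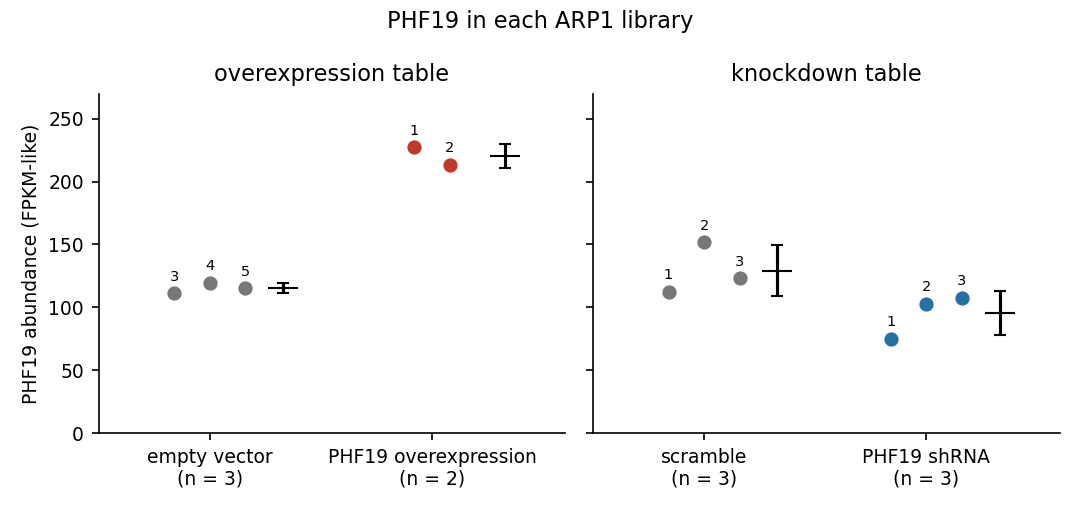
PHF19 abundance in each library, on a linear axis from 0, with replicate numbers beside the points and bars for mean ± SD. The PHF19 overexpression libraries sat at 213 and 227, above the empty vector libraries at 111 to 119, and the PHF19 shRNA libraries at 75.2 to 108, below the scramble libraries at 113 to 152.

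The knockdown comparison asked which transcripts differ when PHF19 is targeted by shRNA. Targets of ATF4, the transcription factor of the integrated stress response, rose together: 26 of 29 listed targets were higher and 0 lower (as a list, adjusted p = 0.566 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose from 7.71 ± 2.69 (SD, n = 3) in scramble to 57.0 ± 11.0 (n = 3) in shRNA libraries, and ASS1, an enzyme of arginine synthesis, from 17.1 ± 9.12 to 173 ± 4.83. NCL, the nucleolar protein nucleolin, fell from 550 ± 34.7 to 349 ± 50.8 and HSPB1, a small heat shock protein, from 985 ± 71.7 to 583 ± 8.45. Their lists, ribosome biogenesis and heat shock, passed camera as lower with 4 of 32 and 5 of 15 members called, as did the proteasome list with 2 of 31, and had adjusted p = 0.699, adjusted p = 0.566 and adjusted p = 0.699 with an estimated correlation. EZH2 was 57.7 ± 3.08 and 52.8 ± 8.98 (adjusted p = 0.588).

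In total 601 of 10900 genes passed, 462 higher and 139 lower in shRNA libraries, against 377 and 206 after quantile normalisation and 417 and 196 after median-of-ratios scaling. A change of at least 2-fold was seen for 133 of the higher and 18 of the lower genes. With the replicate block 894 genes were higher and 401 lower, and 599 of the 601 were among them. Groups did not overlap for 32.0% of genes tested, where chance gives 10%, and 2626 genes had an unadjusted p under 0.05, where chance gives 545. The authors' own p was under 0.05 for 8844 genes of this table. The count fell to 54, 58 and 164 without scramble replicate 1, 2 and 3, and to 285 and 180 without shRNA replicate 2 and 3. Of the 45 named genes past the threshold in this arm, 12, 11 and 17 still passed without scramble replicate 1, 2 and 3, and 37, 28 and 21 without shRNA replicate 1, 2 and 3. The 8 that passed without each library in turn were CHAC1, ALDH2, PIP5KL1, PCK2, SLC6A9, WARS, ALDH1L2 and GPT2.

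The 10 largest rises were ASS1, INHBE, CHAC1, ALDH2, PIP5KL1, PCK2, SLC6A9, DDIT4, SESN2 and DAPK2, with log2 fold changes of 2.07 to 3.44. INHBE, the inhibin beta E subunit, rose from 8.50 ± 4.39 to 59.1 ± 9.01 (log2 fold change 2.79, SE 0.37, adjusted p = 0.0129). ALDH2, mitochondrial aldehyde dehydrogenase, rose from 3.75 ± 0.781 to 30.7 ± 15.1 (2.65, adjusted p = 0.00305). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose from 23.0 ± 9.01 to 110 ± 25.8 (2.26, adjusted p = 0.00957). SLC6A9, a glycine transporter, rose from 4.41 ± 1.11 to 24.3 ± 1.77 (2.24, adjusted p = 0.00126). The mTORC1 inhibitors DDIT4 and SESN2 rose from 60.3 ± 27.8 to 270 ± 86.1 (adjusted p = 0.0419) and from 17.4 ± 6.20 to 79.8 ± 25.7 (adjusted p = 0.0143). ASS1 (3.44, SE 0.43, adjusted p = 0.0152) no longer passed without shRNA replicate 1, 2 or 3 (adjusted p = 0.0810, 0.0559 and 0.0690).

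**Figure D2:**
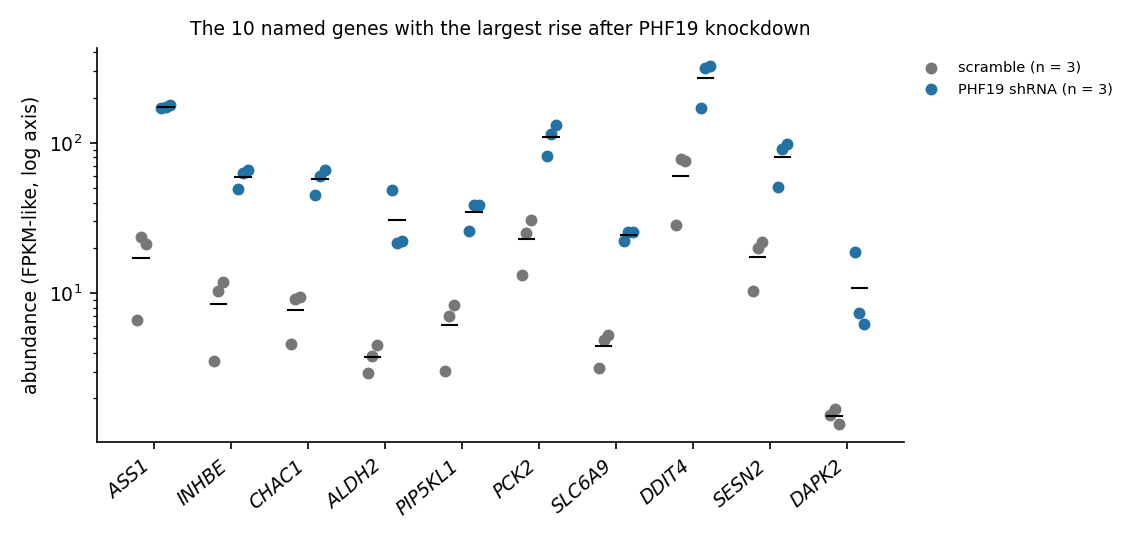
Abundance (log axis) of the 10 genes with the largest rise in each scramble and shRNA library, with a line at each group's mean. CHAC1 went from 7.71 to 57.0 and ASS1 from 17.1 to 173 on average. The groups overlap for none of the 10 genes because the rule for named genes required it.

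The largest falls were smaller. LIPH, a lipase, fell from 5.30 ± 0.622 to 1.49 ± 0.80002 (log2 fold change -1.38, SE 0.22, adjusted p = 0.0141), and CGN, the tight junction protein cingulin, from 7.14 ± 1.78 to 2.32 ± 0.804 (-1.30, adjusted p = 0.0163). DUSP5, a nuclear ERK phosphatase, fell from 110 ± 6.43 to 47.8 ± 16.9 (-1.25, adjusted p = 0.0243). MPP3, TMEM81 and SH2D3A fell with log2 fold changes of -1.14, -1.07 and -1.07. HBA1, an alpha globin gene that shares sequence with HBA2, was listed at 5.65, 4.50 and 5.01 in scramble and at 0, 0 and 2.24 in shRNA libraries (adjusted p = 0.0292). NME1-NME2, a readthrough transcript, and ATAD3B, which has close paralogs, also fell (-1.34 and -1.10) and are uncertain because reads can be shared.

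Among the gene lists, 9 of 29 passed camera with the preset correlation. Of the 10 splits of the 6 libraries into groups of 3, 5 gave as many lists, the real one included. The integrated stress response list rose with a median log2 fold change of 1.26 (26 of 29 called over all genes, 28 with the replicate block, and 29 of 29 adjusted over the list alone, camera adjusted p = 8.72e-24), and its adjusted p = 0.566 with an estimated correlation. WARS, tryptophanyl-tRNA synthetase, rose from 76.7 ± 10.7 to 186 ± 18.8 (1.28, adjusted p = 0.00305), ALDH1L2, a mitochondrial folate enzyme, from 4.33 ± 1.23 to 13.5 ± 1.04 (1.47, adjusted p = 0.0045), and GPT2, an alanine aminotransferase, from 21.3 ± 6.31 to 78.9 ± 16.4 (1.86, adjusted p = 0.00513).

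MYC targets and ribosome biogenesis genes were lower in 32 of 32 cases, with a median of -0.46, of which 4 were called over all genes (9 with the replicate block) and 28 adjusted over the list alone (camera adjusted p = 8.63e-14). The adjusted p = 0.699 with an estimated correlation. The 4 called members, all of which act in the nucleolus, were WDR43 (55.6 ± 4.50 to 36.2 ± 4.42), NCL (log2 fold change -0.66, adjusted p = 0.0324), NOP16 (89.6 ± 16.8 to 55.7 ± 6.76) and MRTO4 (74.6 ± 7.43 to 46.7 ± 10.7). Proteasome subunits were lower in 31 of 31 cases with a median of -0.36, 2 called over all genes (11 with the replicate block) and 17 adjusted over the list alone (camera adjusted p = 4.93e-12, and adjusted p = 0.699 with an estimated correlation). PSMC1, an ATPase of the proteasome base, fell from 140 ± 12.4 to 91.1 ± 6.29 (-0.61, adjusted p = 0.0258), and PSMD12 from 26.1 ± 1.73 to 17.1 ± 2.88 (-0.60, adjusted p = 0.0437). PSMD1 (-0.47) and PSMB6 (-0.55) passed with the replicate block (adjusted p = 0.0338 and 0.0327, against 0.0517 and 0.0520).

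S phase genes were lower in 42 of 45 cases with a median of -0.31, 1 called over all genes (5 with the replicate block) and 0 adjusted over the list alone (camera adjusted p = 6.80e-08, and adjusted p = 0.699 with an estimated correlation). The called member was CDC6, which loads the replicative helicase, at 39.1 ± 0.777 in scramble and 24.8 ± 4.69 in shRNA libraries (-0.65, adjusted p = 0.0354). FEN1 and UHRF1 passed with the replicate block (adjusted p = 0.0431 and 0.0352, against 0.0606 and 0.105). UNG was 47.2 ± 2.85 and 36.4 ± 3.38 (adjusted p = 0.102). Heat shock genes were lower in 14 of 15 cases with a median of -0.54, 5 called over all genes (8 with the replicate block) and 9 adjusted over the list alone (camera adjusted p = 1.47e-07, and adjusted p = 0.566 with an estimated correlation). The called members were HSPB1 (-0.75), HSP90AA1 (-0.65), DNAJA1 (-0.58), HSP90AB1 (-0.58) and CHORDC1 (-0.54), all of them chaperones or co-chaperones.

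Glycolysis genes were lower in 12 of 15 cases with a median of -0.32, 1 called higher and 2 lower over all genes (1 and 4 with the replicate block), and 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000796, and adjusted p = 0.566 with an estimated correlation). PFKL, the liver-type phosphofructokinase, rose from 48.8 ± 3.94 to 76.8 ± 11.996 (0.63, adjusted p = 0.0315), while PFKM, the muscle type, fell from 64.7 ± 8.80 to 41.6 ± 5.18 (-0.62, adjusted p = 0.0356) and PGAM1, phosphoglycerate mutase, from 414 ± 34.5 to 282 ± 32.2 (-0.56, adjusted p = 0.0468). SLC16A1, a lactate transporter, passed with the replicate block (-0.43, adjusted p = 0.0416, against 0.0937). With fry, 3 lists passed: integrated stress response higher, heat shock and glycolysis lower (adjusted p = 0.0405 for each).

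Immediate early genes were lower in 12 of 15 cases with a median of -0.27, 0 called over all genes by limma (3 with the replicate block) and 0 adjusted over the list alone (camera adjusted p = 0.0172, and adjusted p = 0.566 with an estimated correlation). FOSL1 (4.56 ± 1.24 and 2.54 ± 0.494) and FOS (2.44 ± 0.480 and 1.22 ± 1.06), both subunits of AP-1, passed with the replicate block (adjusted p = 0.0417 and 0.0462, against 0.0846 and 0.163). KLF6 was 37.2 ± 3.12 and 29.2 ± 3.89 (adjusted p = 0.154), and DUSP2 11.2 ± 2.38 and 8.08 ± 0.444 (adjusted p = 0.170). PRC2 subunits were lower in 11 of 13 cases with a median of -0.14, 0 called over all genes (2 with the replicate block) and 0 adjusted over the list alone (camera adjusted p = 0.0396, and adjusted p = 0.699 with an estimated correlation). The list holds PHF19, the target of the shRNA, which is 1 of the 2 calls with the replicate block. The list result thus rests in part on the knockdown itself, and no value without PHF19 is given. EED, the subunit that binds methylated histone H3, was 26.2 ± 0.924 and 18.5 ± 3.85 (-0.50, adjusted p = 0.0875, and 0.0470 with the replicate block), and MTF2, another accessory subunit, 6.95 ± 0.445 and 4.87 ± 0.743 (adjusted p = 0.113). RBBP4 was 30.9 ± 1.39 and 26.7 ± 3.30 (adjusted p = 0.352). The PRC2 list did not pass without scramble replicate 3 (adjusted p = 0.0881) or shRNA replicate 1 (0.174), and with a filter at 5 neither it nor the immediate early list passed (0.0549 and 0.1).

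Cytosolic ribosomal proteins were higher in 49 of 50 cases with a median of 0.15, 0 called over all genes (2 with the replicate block) and 0 adjusted over the list alone (camera adjusted p = 0.0396, and adjusted p = 0.799 with an estimated correlation). RPL12 was 1090 ± 134 and 1501 ± 162 (0.46) and RPL13A 1987 ± 395 and 2761 ± 662 (0.47), both past the threshold with the replicate block (adjusted p = 0.0417 and 0.0437, against 0.105 and 0.204). RPLP0 was 1927 ± 137 and 2379 ± 89.0 (adjusted p = 0.211), and RPL3 1333 ± 132 and 1725 ± 319 (adjusted p = 0.220). This list did not pass after median-of-ratios scaling (adjusted p = 0.0820), with pseudocounts of 0.1 and 0.5 (0.0583 and 0.0508), without shRNA replicate 1 (0.922) or without scramble replicate 3, where camera's direction was down (0.669).

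Of 105 listed developmental regulators, the classical targets of Polycomb, 49 were in the knockdown table and 25 had values high enough to be tested. Of these 25, 2 were higher and 0 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.281). Most of the listed targets were thus not tested. HOXB9 rose from 45.2 ± 7.25 to 81.9 ± 4.45 (0.85, adjusted p = 0.0152) and HOXB8 from 3.51 ± 0.829 to 6.22 ± 0.478 (0.69, adjusted p = 0.0486), and HOXB3 was 1.98 ± 0.349 and 3.003 ± 0.165 (adjusted p = 0.128) and DLX2 2.79 ± 0.544 and 3.87 ± 0.216 (adjusted p = 0.190). Of 17 pro-apoptotic genes 1 was higher and 2 lower over all genes (3 and 3 with the replicate block), and 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.394). BMF, a BH3-only protein, rose from 29.7 ± 4.78 to 57.0 ± 15.5 (0.90, adjusted p = 0.0283), while BIK, another BH3-only protein, fell from 3.95 ± 1.12 to 1.05 ± 0.640 (-1.30, adjusted p = 0.0251) and BAK1, a pore-forming effector, from 59.9 ± 2.19 to 39.7 ± 4.11 (-0.58, adjusted p = 0.0267). TNFRSF10B, a TRAIL receptor, passed with the replicate block (0.51, adjusted p = 0.0365, against 0.0844). None of 8 anti-apoptotic genes passed limma over all genes, and 0 adjusted over the list alone (camera adjusted p = 0.911). MCL1 was 204 ± 24.3 and 159 ± 23.8 (adjusted p = 0.178), BCL2L1 10.7 ± 0.980 and 11.5 ± 2.15 (adjusted p = 0.797) and BCL2L2 4.32 ± 0.232 and 6.01 ± 0.527 (adjusted p = 0.126). BIRC2 was 14.4 ± 1.28 and 18.3 ± 2.52 (adjusted p = 0.197), and CFLAR 13.4 ± 2.41 and 11.2 ± 1.75 (adjusted p = 0.443). HIF1A was 7.16 ± 1.54 and 7.14 ± 1.54 (adjusted p = 0.994).

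**Figure D3:**
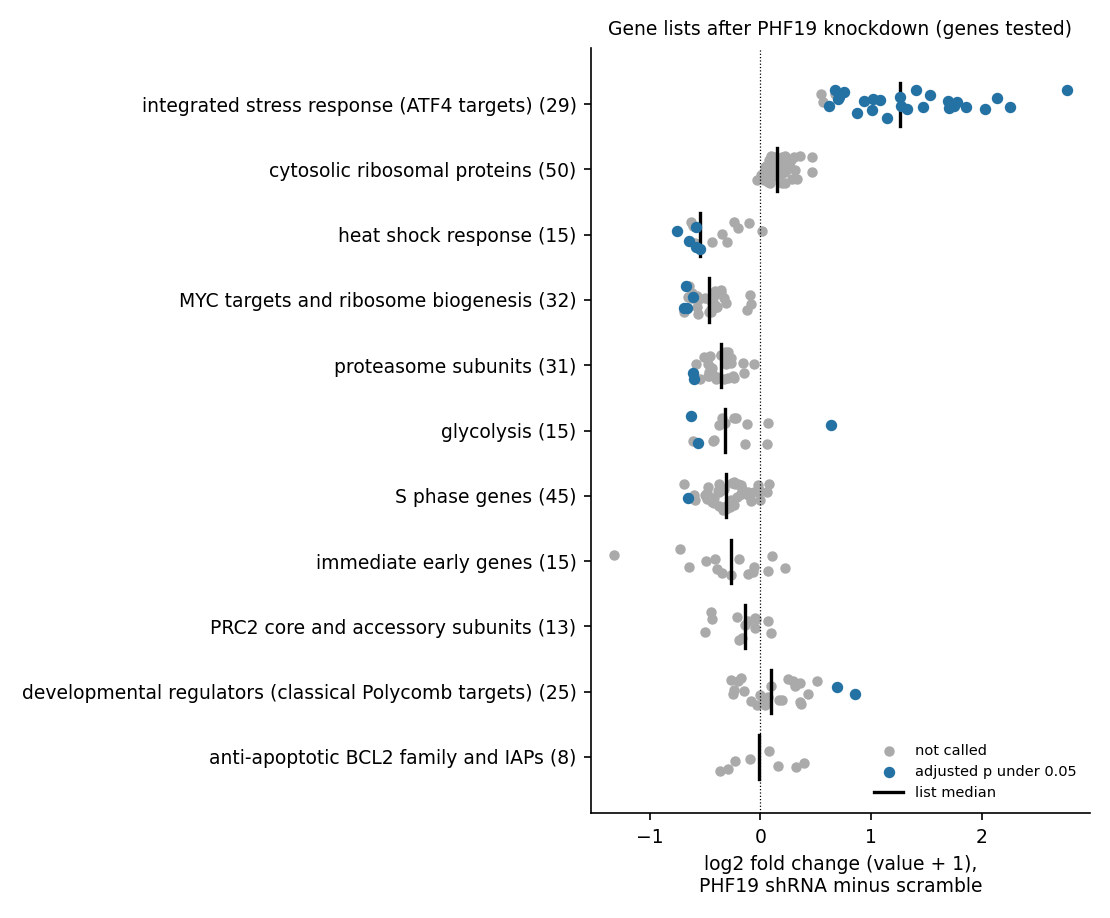
Log2 fold changes (shRNA minus scramble) of the tested members of 11 gene lists, 1 point per gene, coloured where the adjusted p over all genes was under 0.05, with a line at the list median. The integrated stress response list has its median at 1.26, and the medians of heat shock, ribosome biogenesis and proteasome genes lie at -0.54, -0.46 and -0.36.

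The overexpression comparison asked which transcripts differ between sorted PHF19-overexpressing cells and empty vector cells. EGR1, an immediate early transcription factor, rose from 2.68 ± 1.04 (SD, n = 3) to 21.8 ± 0.374 (n = 2), a log2 fold change of 2.67 (SE 0.27, adjusted p = 0.0457). Other genes of this class, induced within minutes of a stimulus, were higher too without passing over all genes: FOS was 1.92 ± 1.38 and 56.3 ± 3.43 (4.42, adjusted p = 0.0604) and DUSP1 5.19 ± 2.06 and 48.1 ± 2.78 (3.05, adjusted p = 0.0696). The labels name sorting before RNA extraction for cells overexpressing PHF19, and whether empty vector cells were sorted is not stated here. An effect of PHF19 on these genes therefore cannot be told apart from sorting or from what the description letters mark. UPP1, uridine phosphorylase, rose from 11.4 ± 0.470 to 28.0 ± 1.22 (1.22, adjusted p = 0.0287) and ZFP36L2, an mRNA-decay factor, from 51.4 ± 2.69 to 118 ± 8.01 (1.18, adjusted p = 0.0314). UNKL fell from 16.98 ± 0.371 to 5.54 ± 0.198 (-1.46, adjusted p = 0.0159), DYNC1H1, the dynein heavy chain, from 17.6 ± 0.548 to 7.55 ± 0.448 (-1.12, adjusted p = 0.0419) and HUWE1, a ubiquitin ligase, from 38.0 ± 0.115 to 18.6 ± 0.435 (-0.99, adjusted p = 0.0344).

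In total 94 of 10279 genes passed, 63 higher and 31 lower in overexpression libraries, and 82 of the 94 were listed at exactly 0 in every library of a group (56 higher and 26 lower). The authors' own p was at least 0.05 for 68 of these 82 genes. It was under 0.05 for 1426 genes, and for 348 after Benjamini-Hochberg adjustment, with the balance turned round by group means (119 higher, 223 lower and 6 equal). Among the 12 calls with no 0, 7 were higher and 5 lower: beside the genes above and PHF19 these were CCDC57 (2.11, authors' p 0.269), TOMM7 of the mitochondrial import complex (1.21, authors' p 0.834), CTXN1 (1.09, authors' p 5.2e-06), TAF8 of the general factor TFIID (-1.28, authors' p 0.403) and an uncharacterised locus. When genes listed at 0 in any library were left out, 0 of 8665 genes passed limma, with 1201 at an unadjusted p under 0.05, and adjusted p for EGR1 and UNKL was 0.101. Groups did not overlap for 34.2% of genes, where chance gives 20%, and 1185 genes had an unadjusted p under 0.05, where chance gives 514. Leaving out empty vector replicate 5, which stood apart from all other libraries on the second principal component (78.5, against -42.9 to 2.83) and lay at 32.9 on the first (overexpression 38.7 and 39.9, other empty vector libraries -68.0 and -43.5), gave 350 genes (258 higher and 92 lower). The balance of directions turned round without overexpression replicate 1 (50 higher and 98 lower, 148 in all), without overexpression replicate 2 (54 and 77) and with a filter at 5 (17 and 19). EGR1, UPP1, ZFP36L2, CCDC57, CTXN1, TOMM7, UNKL, TAF8, DYNC1H1 and HUWE1 each passed without empty vector replicate 5 and failed without any other single library (adjusted p 0.0692 to 0.217).

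The genes listed at 0 are given as values. UAP1, an enzyme of UDP-GlcNAc synthesis, was listed at 0 in all 3 empty vector libraries and at 198 and 183 in overexpression libraries, and SDHD, a subunit of respiratory complex II, at 0 and then at 101 and 97.5. The genes ECHS1, RABL6, PSME3, UBA2, GRWD1 and WDR43 were likewise at 0 in every empty vector library and between 42.3 and 93.5 in overexpression libraries. RPL11, a ribosomal protein, was listed at 1933, 1733 and 2006 in empty vector libraries and at 0 in both overexpression libraries. UTP3 (145, 117 and 71.6), CCR10 (48.1, 56.9 and 77.7), EMC3 (45.5, 43.0 and 40.8), SURF2, CCAR1, MAPKAPK5, PAAF1, TCEB3 and RAD9A showed the same listing.

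Of 28 lists 5 passed camera with the preset correlation, all with higher values, and each had adjusted p = 0.778 with an estimated correlation. Leaving out empty vector replicate 3, 4 and 5 gave 3, 2 and 13 lists, and leaving out overexpression replicate 2 gave 1. Of the 13 without empty vector replicate 5, 8 were higher and 5 lower, the lower ones being S phase (adjusted p = 8.62e-05), proteasome (0.0209), ribosome biogenesis (0.0299), PRC2 (0.0308) and heat shock genes (0.0469). These 5 values are camera's at the preset correlation, and none with an estimated correlation is given for that setting. With all libraries the estimated correlation gave these 5 lists adjusted p of 0.778 to 0.977. The PRC2 list holds EZH1, which was listed at 0 in both overexpression libraries. Immediate early genes were higher in 14 of 15 cases with a median of 0.82, 1 called over all genes and 8 adjusted over the list alone (camera adjusted p = 9.78e-06), and this list also passed camera without each library in turn. The mean log2 level of its 13 members with no 0 was 5.02 and 5.07 in overexpression libraries and 3.13 to 3.76 in empty vector libraries. This list was fixed in advance as a technical one, and its rise cannot be told apart from sorting or the description letters. Fry passed 6 lists, all as higher: immediate early genes (adjusted p = 0.0421), pro-apoptotic genes and H3K27 and H3K36 regulators (both 0.00398), oxidative phosphorylation (0.00682), developmental regulators (0.0251) and histones (0.0311). Of these, H3K27 and H3K36 regulators and histones had 9 of 17 negative members each and medians of -0.04 and -0.12, and with genes listed at 0 left out 9 of 14 and 7 of 9 were negative. The integrated stress response, ribosomal, cholesterol and hypoxia lists did not pass fry (adjusted p = 0.378, 0.585, 0.165 and 0.490). FOSB was 1.93 ± 1.15 and 18.1 ± 2.91 (adjusted p = 0.120). Integrated stress response genes were higher in 26 of 28 cases with a median of 0.61, 0 called over all genes by limma and 0 adjusted over the list alone (camera adjusted p = 0.00684, but 0.0640 without empty vector replicate 3 and 0.237 without overexpression replicate 2). WARS was 70.7 ± 12.2 and 114 ± 8.91 (adjusted p = 0.343), TRIB3 14.4 ± 5.22 and 32.5 ± 4.66 (adjusted p = 0.364), PSAT1 76.6 ± 14.97 and 121 ± 3.65 (adjusted p = 0.381) and CEBPB 9.74 ± 3.31 and 20.4 ± 0.704 (adjusted p = 0.384).

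**Figure D4:**
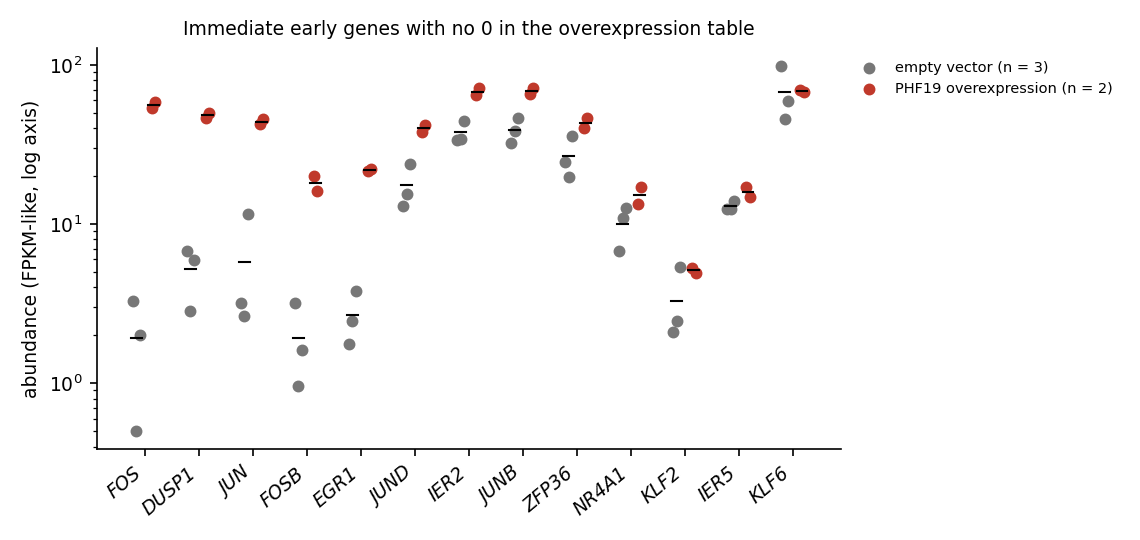
Abundance (log axis) of the 13 immediate early genes with no 0, in each empty vector and PHF19 overexpression library, with a line at each group's mean. FOS, with 1.92 and 56.3 on average, is the member with the largest difference, and EGR1 (2.68 and 21.8) is the member that passed over all genes. The description letters split with the group, and sorting before RNA extraction is named for the overexpressing cells.

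Cytosolic ribosomal proteins were higher in 35 of 41 cases with a median of 0.40, 0 called higher and 1 lower over all genes (RPL11, listed at 0), and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00684, and 0.778 with an estimated correlation). RPS4X was 1148 ± 115 and 1764 ± 9.21 (adjusted p = 0.215) and RPLP1 3310 ± 400 and 5395 ± 421 (adjusted p = 0.236). RPL27 was 2863 ± 169 and 3752 ± 8.85 (0.39, adjusted p = 0.289), and its difference was -0.0234 after quantile normalisation. Fry's direction for this list was down, against up for its median and camera, and the call ended under quantile normalisation (adjusted p = 0.587), without empty vector replicate 4 (0.0570) and without overexpression replicate 2 (0.193). Cholesterol biosynthesis genes were higher in 21 of 22 cases with a median of 0.27, 0 called by limma and 0 adjusted over the list alone (camera adjusted p = 0.0323, and 0.778 with an estimated correlation). SREBF2, which drives sterol synthesis genes, was 58.7 ± 14.7 and 94.6 ± 0.327 (adjusted p = 0.393), and MVK, mevalonate kinase, 4.66 ± 0.754 and 7.75 ± 1.21 (adjusted p = 0.382). The sterol enzymes CYP51A1 and SQLE were 24.2 ± 1.54 and 30.5 ± 0.399 (adjusted p = 0.398) and 19.95 ± 1.46 and 24.5 ± 0.554 (adjusted p = 0.460). Hypoxia genes were higher in 22 of 26 cases with a median of 0.51, 0 called by limma and 1 adjusted over the list alone (camera adjusted p = 0.0468, and 0.778 with an estimated correlation). ADM, adrenomedullin, was 94.7 ± 6.97 and 159 ± 6.51 (0.74, adjusted p = 0.152), PGK1 438 ± 71.6 and 607 ± 2.89 (adjusted p = 0.398) and HIF1A itself 8.14 ± 1.82 and 6.15 ± 0.0538 (-0.34, adjusted p = 0.579). FAM162A was 131 ± 33.1 and 209 ± 14.98 (adjusted p = 0.405), and EGLN1, a HIF prolyl hydroxylase, 14.6 ± 2.64 and 23.8 ± 5.22 (adjusted p = 0.409). Leaving out any single library other than empty vector replicate 5 ended the cholesterol call (adjusted p 0.0570 to 0.197) and the hypoxia call (0.0906 to 0.418). A filter at 5 ended both (0.0722 and 0.108), quantile normalisation the cholesterol call (0.0505), and pseudocounts of 0.1 and 0.5 the hypoxia call (0.0606 and 0.0507).

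Of 10 PRC2 subunits, PHF19 was called higher and EZH1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.177). EZH1, the paralog of EZH2, was listed at 12.1, 14.7 and 15.6 in empty vector libraries and at 0 in both overexpression libraries. EZH2 was 54.5 ± 7.51 and 52.5 ± 2.54 (-0.05, adjusted p = 0.928), MTF2 8.14 ± 0.341 and 7.16 ± 0.999 (adjusted p = 0.682) and JARID2 5.24 ± 1.005 and 4.375 ± 0.401 (adjusted p = 0.720). RBBP4, a histone-binding subunit, was 52.8 ± 26.7 and 31.2 ± 6.62 (adjusted p = 0.731). Without empty vector replicate 5 the PRC2 list passed as lower at the preset correlation (camera adjusted p = 0.0308). No value with an estimated correlation is given for that setting, and with all libraries it was adjusted p = 0.778 by camera. EZH1, with its listed zeros, is a member of this list. With genes listed at 0 left out and all libraries kept, the median of the 9 other members was -0.05 (camera adjusted p = 0.617). Of the 105 listed developmental regulators 25 were in the overexpression table and 19 were tested. Of these 19, 1 was called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.522). HOXB4 and HOXB5 were listed at 0 in all empty vector libraries and at 5.82 and 5.44, and at 1.52 and 1.08, in overexpression libraries. MEIS2 was 3.66 ± 0.371 and 2.29 ± 0.0846 (adjusted p = 0.384) and MSX1 2.66 ± 0.234 and 4.05 ± 0.587 (adjusted p = 0.421). TBX2 was 1.02 ± 0.304 and 1.83 ± 0.188 (adjusted p = 0.475), and SIX2 6.39 ± 1.34 and 8.64 ± 0.231 (adjusted p = 0.524). None of 6 anti-apoptotic genes passed limma over all genes, and 0 adjusted over the list alone (camera adjusted p = 0.904), with BCL2L1 at 9.35 ± 1.996 and 11.9 ± 1.13 (0.34, adjusted p = 0.579). CFLAR was 13.001 ± 8.57 and 20.4 ± 0.0248 (adjusted p = 0.654), XIAP 6.49 ± 0.492 and 5.61 ± 0.988 (adjusted p = 0.697) and BIRC3 9.52 ± 5.65 and 7.03 ± 1.62 (adjusted p = 0.854).

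Myeloid marker transcripts were present in overexpression replicate 2: S100A8 and S100A9, abundant in neutrophils and monocytes, were at 24.3 and 27.2 there, at 0.302 and 0.507 in replicate 1 and at 0 in every empty vector library. In replicate 1, 6 of the 8 myeloid genes of the table were also higher than in every empty vector library. This difference between the overexpression libraries accompanies each gene group above. Quantile normalisation moved the median log2 fold change of all genes in this arm from 0.0873 to -0.0448.

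The arms were then compared to ask whether genes move in opposite directions when PHF19 is raised and lowered. Of 9307 genes tested in both, GRWD1 and WDR43, both ribosome biogenesis factors, were called higher with overexpression and lower with knockdown, where 0.741 are expected by chance. In the knockdown arm GRWD1 fell from 132 ± 7.68 (n = 3) to 66.5 ± 13.9 (n = 3) and WDR43 as given above, and in the overexpression table both were listed at 0 in every empty vector library, with GRWD1 at 66.7 and 65.4 and WDR43 at 42.3 and 45.1 in overexpression libraries. No gene was called lower with overexpression and higher with knockdown (1.16 expected), by limma in each arm. IGFLR1 and SLC48A1 were higher in both (2.28 expected) and UTP3 lower in both (0.377 expected), and each of these 3 was listed at 0 in a whole group of the overexpression table. Since all 5 shared calls, and 82 of the 94 calls of the overexpression arm, rest on such zeros, these overlaps leave open whether the arms share or oppose changes. With genes listed at 0 left out, 0 genes were called in the overexpression arm by limma (1201 at an unadjusted p under 0.05). When empty vector replicate 5 was left out as well, 1349 genes were called and 11 genes were called in opposite directions, so a single library moves these counts. The count of opposite calls, 2, became 6 and 4 without overexpression replicate 1 and 2. It became 0 without scramble replicate 1 or 2, and 1 without scramble replicate 3 or shRNA replicate 2 or 3.

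The genes called higher with knockdown were, as a set, also higher with overexpression: 291 of 373 had a positive log2 fold change there, with a median of 0.34 (camera adjusted p = 0.000226, and adjusted p = 0.960 with an estimated correlation). The genes called lower with knockdown were positive in 62 of 121 cases (camera adjusted p = 0.483). Across 9307 genes, which are not independent replicates, the log2 fold changes of the arms correlated at 0.149 (Spearman) and 0.0742 (Pearson), and at 0.194 and 0.190 across the 7928 genes with no 0.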

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

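The fits that leave out genes listed at 0 or treat zeros as missing, and those combining left-out genes or the replicate block with left-out replicates, were chosen after the results were seen; all others were planned. With fewer genes and libraries the multiple-testing burden and degrees of freedom change; otherwise the cause was not tested. Unstated read depth limits every value at the low end.

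For overexpression, where 94 genes, 5 lists and a PHF19 log2 fold change of 0.93 are the values reported, a filter at 5 gave 36 genes (17 higher, 19 lower), 3 lists and PHF19 adjusted p = 0.0650 (0.93), a pseudocount of 0.1 gave 61 genes and PHF19 0.0532 (0.93), and library weights 1729 genes (1232 higher, 497 lower). PHF19 also missed the threshold without trend and robust variances (0.93, adjusted p = 0.0781), after quantile normalisation (0.75, 0.166; 3 lists) and after median-of-ratios scaling (0.85, 0.0547). Leaving out genes with any 0 gave 0 genes (1201 at an unadjusted p under 0.05) and PHF19 0.156 (0.93). Leaving out genes listed at 0 that reach 10 elsewhere gave 27 genes and PHF19 0.0744 (0.93), and zeros as missing values 27 and 0.0741 (0.93). With no 0 and without overexpression replicate 2 the values were 0 genes by limma (348 at an unadjusted p under 0.05) and PHF19 0.97 (adjusted p = 0.999), and with no 0 and without empty vector replicate 5 they were 1349 genes and 11 lists. Leaving out each library in turn gave 107 to 350 genes, 1 to 13 lists, and PHF19 0.88 to 0.97 (adjusted p 0.0349 to 0.264). An estimated correlation left 0 lists, with limma's camera. No paired analysis was possible because the empty vector and overexpression libraries share no replicate number.

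For knockdown, where 601 genes and 9 lists are reported, no filter gave 269 genes, library weights 3161, the replicate block 1295, a 2-fold limit 151 and an adjusted p under 0.01 gave 41, all higher. The block without replicate 1 of both groups gave 2196 genes. PHF19 passed with library weights (-0.45, adjusted p = 0.00747), the replicate block (-0.44, 0.0445) and the block without replicate 1 (-0.37, 0.00305); the block changed no call of a named gene other than those given with its value. Leaving out each library gave 54 to 629 genes, 9 to 12 lists and PHF19 -0.54 to -0.28 (adjusted p 0.154 to 0.400). An estimated correlation left 0 lists and fry 3. The block added the G2 and M phase and plasma cell lists (both lower, adjusted p = 0.0476, and adjusted p = 0.736 with an estimated correlation).

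Genes called in opposite directions, 2 as reported, numbered 19 with library weights in the overexpression arm and 10 in the knockdown arm, 5 with the replicate block, 10 with the block without replicate 1, 1 with no filter in the knockdown arm, 0 under each exclusion of zeros and 11 with no 0 and without empty vector replicate 5. Leaving out a library gave 3 to 6 (overexpression arm) and 0 to 2 (knockdown arm). No number expected by chance and no count of calls in the same direction is given for these settings. A higher count is thus not evidence of opposition.

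Signs turned for 5 named genes, none of them called. With overexpression these were RPL27 after quantile normalisation (-0.0234), BIRC3 with library weights (0.180) and without empty vector replicate 5, zeros kept or not (0.132; -0.531 to 0.132 over left-out libraries), and EZH2 without empty vector replicate 3 (0.0292) and without overexpression replicate 2, zeros kept or not (0.00341; -0.161 to 0.0292 over left-out libraries). With knockdown they were HIF1A with library weights (0.0319) and without scramble replicate 2 (0.0729), scramble replicate 3 (0.0880) and shRNA replicate 1 (0.165; -0.170 to 0.165 over left-out libraries), and BCL2L1 without shRNA replicate 1 (-0.0412; -0.0412 to 0.211 over left-out libraries). BIK, HBA1 and NME1-NME2 lost their calls in the block without replicate 1 (adjusted p = 0.151, 0.247 and 0.423). Of 1143 values of named genes under alternatives in the knockdown arm, 904 kept direction and side of the threshold, 186 lost and 48 gained a call; of 1080 in the overexpression arm, 930, 106 and 37. A planned fit of all 4 groups together was not run, since the tables were normalised separately.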

Other observations

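Further genes rose with knockdown, all but STC2 outside the lists described so far for that arm. They were picked after the results were seen, as members past the threshold of lists that did not pass as a whole. CCNG1, a p53 target and cyclin, rose from 96.04 ± 5.82 (SD, n = 3) to 233 ± 36.1 (n = 3), with a log2 fold change of 1.26 (limma adjusted p = 0.00305). STC2 and VEGFA, secreted hypoxia-responsive factors, rose from 12.9 ± 3.52 to 46.3 ± 15.2 and from 16.7 ± 3.19 to 36.2 ± 11.5, while 16 of 25 hypoxia genes were negative and the list did not pass (camera adjusted p = 0.162). STC2 is also a member of the integrated stress response list, so its rise is part of that result. EDEM1 (1.05) and ERN1 (1.04), which act in endoplasmic reticulum quality control, rose while 13 of 22 genes of the unfolded protein response were negative (camera adjusted p = 0.336). HLA-B (0.67) and HLA-F (0.63) of MHC class I rose, with 15 of 20 antigen presentation genes positive (camera adjusted p = 0.146). EIF4EBP1 (0.79), KDM4A (0.80) and STAT2 (0.85) rose, and CAV1 (-0.82) and TRIAP1 (-0.60) fell. KRT18, an epithelial keratin, fell from 11.1 ± 1.84 to 5.08 ± 0.382, and CD68 from 3.39 ± 0.381 to 1.61 ± 0.220.

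The remaining lists did not pass limma's camera. In the knockdown arm adjusted p was 0.0968 for G2 and M phase, 0.0683 for plasma cell identity, 0.155 for PRC1, 0.266 for H3K27 and H3K36 regulators, 0.209 for CDK inhibitors and for NF-kB targets, 0.714 for interferon-stimulated genes and for histones, 0.461 for p53 targets, 0.281 for PI3K and mTOR, 0.146 for cholesterol synthesis, 0.271 for drug response, 0.465 for oxidative phosphorylation and 0.336 for B cell markers. In the overexpression arm glycolysis and oxidative phosphorylation were both at 0.0594, interferon-stimulated genes at 0.140 and the others between 0.177 and 0.904. With genes listed at 0 left out, interferon-stimulated genes passed (15 of 16 positive, median 0.34, adjusted p = 0.00762), with 0 of 16 called by limma and adjusted p = 0.833 with an estimated correlation. Fewer than 5 members were tested for myeloid, stromal, epithelial, T and NK cell, mitochondrial and nuclear-retained lists in both arms, and for antigen presentation in the overexpression arm. The myeloid list passed as higher with overexpression with no filter (8 genes, camera adjusted p = 0.00350, and adjusted p = 0.799 with an estimated correlation) and without overexpression replicate 1 (1.66e-13, and adjusted p = 0.462 with an estimated correlation).

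Tests on zeros, myeloid genes and stress genes below were chosen after the results were seen; the comparisons with other splits of the libraries were planned. The first pattern is the exact zeros in the overexpression table. The 56 genes called higher from 0 in every empty vector library had a median level of 11.6 in scramble libraries of the same line (52 in that table), and their overexpression levels tracked the scramble levels across genes (Pearson 0.925), consistent with failed estimates in the authors' table. Silence of these genes without PHF19 overexpression is argued against, as 50 of the 52 reached 1 or more in scramble libraries. For the 26 genes at 0 in both overexpression libraries, the authors' p was at least 0.05 for 22 and under 0.05 for 4. Zeros of genes that reach 10 or more in another library occurred in every library of this arm. They numbered 441 to 454 in empty vector libraries and 301 and 364 in overexpression libraries, so they are not particular to a group. Silence of the 26 genes under PHF19 overexpression stays open, since the authors' test is not stated.

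The second pattern is the myeloid transcripts of overexpression replicate 2. Of 14 listed myeloid genes 8 were in the table, 7 of them highest in that library, with a median log2 ratio of 2.54 over replicate 1; LYZ was 6.17 against 0.396 and MPO 6.70 against 0.169, and HBB, chosen after its values were seen, 12.9 against 3.09 (0 to 0.755 in empty vector libraries). RNA of other cells in that library is a candidate explanation, although the cells had been sorted, and the line itself lists CD68 at 3.13 to 3.83 and CD33 at 2.59 to 3.16 in scramble libraries. PHF19 overexpression as the source stays open: 2 of the 8 reached 1 in replicate 1, but 6 of the 8 were higher there than in every empty vector library. These counts rest in part on zeros, since 6 of the 8 were listed at 0 in every empty vector library. CD68 was at 0 in replicate 1 too, and given its scramble levels its zeros may be failed estimates. CD33 was higher in both overexpression libraries (10.5 and 15.2) than in empty vector libraries (2.44 to 4.51).

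The third pattern is the rise of integrated stress response genes with knockdown. The gap between the lowest shRNA and highest scramble library in mean log2 level was 0.769, and the ranges within groups were 0.506 and 0.509, so the difference exceeds the spread between libraries. By replicate number shRNA lay above scramble by 1.28, 1.33 and 1.28, yet spread between cultures stays open, as no label says that the numbers mark pairs or separate cultures. Scaling is argued against as the whole cause, since the median stayed at 1.16 after quantile normalisation with 26 genes still called. An effect of PHF19 level with opposite signs in the arms would need the list to be lower with overexpression. The list was higher there by 0.622 (log2), the other way. This is less than the 1.03 range of the empty vector libraries, so such an effect stays open. Culture conditions and off-target effects of the hairpins were not tested.

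Of the 10 splits of the 6 knockdown libraries into groups of 3, only the real split, 1 of 10, gave as many genes (601 by limma, and 1 for the highest other split), and 5 gave as many lists (9 for the real split, 13 for the highest other). Among the 4 splits that part all 3 pairs, the real split gave 1295 genes with the replicate block and the highest other 0. The number of lists past the threshold thus did not set the real split apart. The largest absolute list median in another split was 0.303 for proteasome genes (0.359 in the real split) and 0.313 for ribosome biogenesis (0.462). It was 0.267 for heat shock (0.543) and 0.720 for the integrated stress response (1.265). With 10 splits no share under 0.05 can arise.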
